A study of Mus with 8 samples.

How the data were processed

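Gene expression was measured in B16F10 cells, a mouse melanoma line that makes melanin, kept for 48 h in medium alone or in medium with Butyroside D. There were 8 samples, 4 labelled as medium controls and 4 labelled with 2 µM of the compound, each on 1 Mouse Clariom S array. This array reads whole-transcript probes and summarises them per transcript cluster, which stands for a gene in most cases. The treatment note of the control samples names 0.2 µM beside the untreated state, while their titles and source fields give medium only, and they were used as controls.

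Per the submitters' processing notes, Affymetrix Expression Console, RMA and Transcriptome Analysis Console were used, with no version, role or order given. The deposited value table holds log2 signals, 1 column per array, on the scale that RMA gives. The genome build and the annotation release are not given in the sources used here, so no coordinates are printed. The second source was the authors' deposited table of the comparison, which gives for each transcript cluster the log2 average of each group. It also gives a signed linear fold change, here called a score because values below 1 are written as negative inverses, by the authors' own convention per the file headers. Its p-value and its FDR-adjusted p-value came from a test that the authors' file headers do not name. The log2 of the fold change was within 0.0159 of the difference of the 2 averages for every transcript cluster.

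The authors' averages were set against the array values before use. The control average of the authors' deposited table lay within 0.01 of the Tukey biweight mean of the 4 control arrays for 22197 of 22206 transcript clusters. The treated average of the authors' deposited table lay within 0.01 of the same mean of the 4 treated arrays for 533 of them, or 2.40%, with a median absolute difference of 0.22 on the log2 scale. None of the 255 combinations of the 8 arrays came closer to that treated average than a median absolute difference of 0.17. The array values were therefore the main source, as fixed in the design for a table with no values per sample, and the authors' deposited table is reported separately and by name.

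From the 28846 features in the value table, 6640 control probe sets were set aside, which left 22206 transcript clusters. Of these, 21367 carry 1 gene symbol, 836 carry several and 3 carry none, and none of those with several is named. RefSeq's mouse gene table (assembly GRCm38.p6) holds 19885 of the single symbols and 870 more as synonyms, and 612 were not matched. Symbols are printed as the deposited table writes them. Ccnd1, which was due to be named, shares its transcript cluster with a microRNA and has no value here.

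Treated minus control was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment over the 22206 transcript clusters and a threshold of 0.05. No block was used, since the labels do not tie equal replicate numbers to a shared culture. The 37 gene lists, of 10 to 28 measured genes each, held 747 genes, of which 707 were measured. They were tested with camera at a preset inter-gene correlation of 0.01 on 1 transcript cluster per gene, with adjustment over the lists. Members were also adjusted over the list alone. Since the authors' deposited table has no replicates to test, a list's median in it is given with its percentile among 10000 random lists of the same size, matched on mean signal. Random lists hold unrelated genes, so this percentile is too extreme for a list whose genes vary together, and it is no p-value.

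The samples, tests, lists, alternatives and naming rule were fixed before the data were examined. The rule took the 12 highest and the 12 lowest fold changes among transcript clusters with 1 symbol that is not a predicted, clone or receptor-family name. It asked for a mean in the higher group at or above 4.21, the limit below which transcript clusters were taken as dim, an adjusted p under 0.05, and all arrays of a group above all of the other. It also took up to 4 members with the smallest p from each list, and 12 fixed genes, some of which are not reported here. Using the same rule on the fold changes and FDR of the authors' deposited table was chosen after its values were seen.

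The test was tried on simulated data for this comparison, with 200 of 22206 transcript clusters changed and the spread of these arrays, which was 0.16 within close pairs and 0.33 between pairs (SD, log2). With 8 independent simulated arrays the fit called 115 transcript clusters on average, 7.6 of them falsely. When the simulated arrays came in close pairs, as the real ones do, it called 1241 on average, 1107 of them falsely. With the pair as a random block the simulated fit called 100.0 on average, 14.4 falsely, and found 29.1% of the changes of 1 on the log2 scale and 98.3% of those of 2. With means of the pairs it called 78.4, of which 2.7 were false. Every simulated transcript cluster had this same spread in both groups. In the real arrays, different pairs correlated at 0.986 in the treated and 0.992 in the control group. The 8-array fit without a block called 26 on the real arrays, so the simulated rates cannot be carried over to them.

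Array values give no counts, so the precision is limited by the number of arrays, 4 in each group, and further by their fall into 2 close pairs per group. The alternatives covered normalization between arrays, filters on dim transcript clusters, the variance model, array weights, the features tested, the replicate number as a block, each array left out, the list test, a fold limit inside the test, and the authors' deposited table as the source. The close pair as a random block (duplicateCorrelation), means of pairs and fits without a pair were added after seeing the data. Plots were drawn with matplotlib 3.10.9.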

Results

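Transcript signals were compared between B16F10 mouse melanoma cells labelled as kept for 48 h with 2 µM Butyroside D and cells kept in medium alone, with 4 arrays in each group. The comparison asks which transcripts differ in this pigment-making tumour line when the compound is present. The median log2 signal over 22206 transcript clusters was between 5.30 and 5.44 in all 8 arrays. The labels do not say whether the arrays came from separate cultures, so p-values measure only the spread between these arrays, which can be technical.

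The 8 arrays fell into 4 close pairs. Control arrays 1 and 2, control arrays 3 and 4, treated arrays 1 and 2, and treated arrays 3 and 4 each correlated with their partner at 0.997 to 0.998 across transcript clusters, and arrays of different pairs at 0.986 to 0.993. Treated arrays 3 and 4 were closer to the controls (0.993) than to treated arrays 1 and 2 (0.986). The first principal component held 47.1% of the variance and set treated arrays 1 and 2 apart from the other 6. The second held 21.4% and separated the control pairs, and the third held 19.2% and separated all 4 control from all 4 treated arrays. With the pair as a random block in limma, the correlation within pairs was 0.808. Each value below with n = 4 therefore rests on 2 close pairs.

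**Figure D1:**
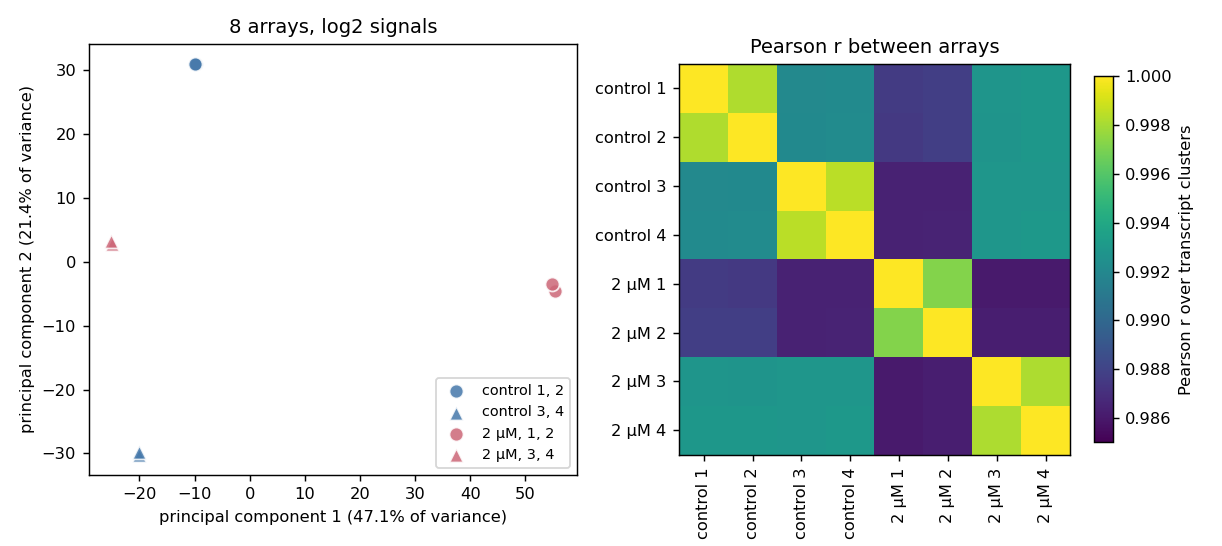
Left, the 8 arrays on the first 2 principal components of the log2 signals, with the share of variance on each axis; the symbols of a pair overlap. Right, Pearson r between arrays across 22206 transcript clusters; partners reach 0.997 to 0.998 and other arrays 0.986 to 0.993.

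In the 8 arrays, the gene with the highest fold change among those past the threshold was Myeov2 (now Cops9, a subunit of the COP9 signalosome), which rose 4.45-fold, from a log2 signal of 7.35 ± 0.59 (SD, n = 4) to 9.51 ± 0.27 (SD, n = 4). Ptgds, which makes prostaglandin D2, rose 2.51-fold, and Cpe, a carboxypeptidase that trims prohormones, rose 2.41-fold, from 7.82 ± 0.11 to 9.09 ± 0.13 (SD, n = 4 each). The tetraspanin Tspan6 rose 2.33-fold, from 5.42 ± 0.14 to 6.64 ± 0.09 (SD, n = 4 each). The genes that fell included Pygl, the liver form of glycogen phosphorylase, and Usf1, a helix-loop-helix transcription factor, at 0.514 and 0.544 of the control level.

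Limma called 26 transcript clusters, 17 higher and 9 lower in the treated arrays, of which 15 differed at least 2-fold (11 higher, 4 lower). The 4 lower ones were Fam214b, Cntnap4, Gm5142 and Gm4297. They, and Gstt2, Esp8 and Acyp2 among the 11 higher, had a group mean below the background level given below. Their 2-fold size is therefore uncertain. With each array centred on its median, 40 transcript clusters were called higher and 8 lower. All 26 had no overlap between the 4 treated and the 4 control arrays, a state that 12.9% of all transcript clusters showed. Chance gives it to 2.86% only if the 8 arrays are independent. With close pairs the share by chance is higher, so the 12.9% cannot be read as an excess. The smallest adjusted p was 0.0170 (limma, Benjamini-Hochberg), shared by Cpe, Tspan6 and the predicted gene Gm4297. With the pair as a random block, limma called 0 transcript clusters, with 890 at an unadjusted p under 0.05 against 3977 without the block. The 890 are a share below 0.05 of the 22206 tested, which chance alone can give. Leaving out any 1 array left 0 calls, except that 5 were called without treated array 4.

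The other named genes that rose were Ppdpf, by 1.14 on the log2 scale, Ndufb6, a complex I subunit, by 1.07, Gstt2, a theta-class glutathione transferase, Esp8 and Acyp2. Fam213a (now Prxl2a), a peroxiredoxin-like protein, rose by 1.05. Hsd17b10, a mitochondrial dehydrogenase, rose by 0.97 and Psenen, a gamma-secretase subunit, by 0.93. The standard errors of these 8 changes lay between 0.11 and 0.16, and their adjusted p between 0.0230 and 0.0423. Cntnap4 and Fam214b fell, Amer1 (an inhibitor of WNT signalling) fell by 0.99, Pygl fell by 0.96, Usf1 fell by 0.88 and the integrin Itgb7 fell by 0.84 on the log2 scale. Their standard errors lay between 0.12 and 0.16 and their adjusted p between 0.0284 and 0.0463. Outside the naming rule, Taf10, Rpl37a, Fam104a, Recql4 and Gm11808 were higher, and Gm5142, Vmn2r53 and Gm4297 lower. Mean signals were below the highest antigenomic background median of the 8 arrays, 5.17, in controls for Acyp2, in treated arrays for Fam214b and Gm4297, and in both groups for Gstt2, Esp8, Cntnap4, Vmn2r53 and Gm5142, so no size is given for these genes. None of these genes passed the threshold with the pair as a random block, where the smallest adjusted p was 0.279 (Myeov2).

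**Figure D2:**
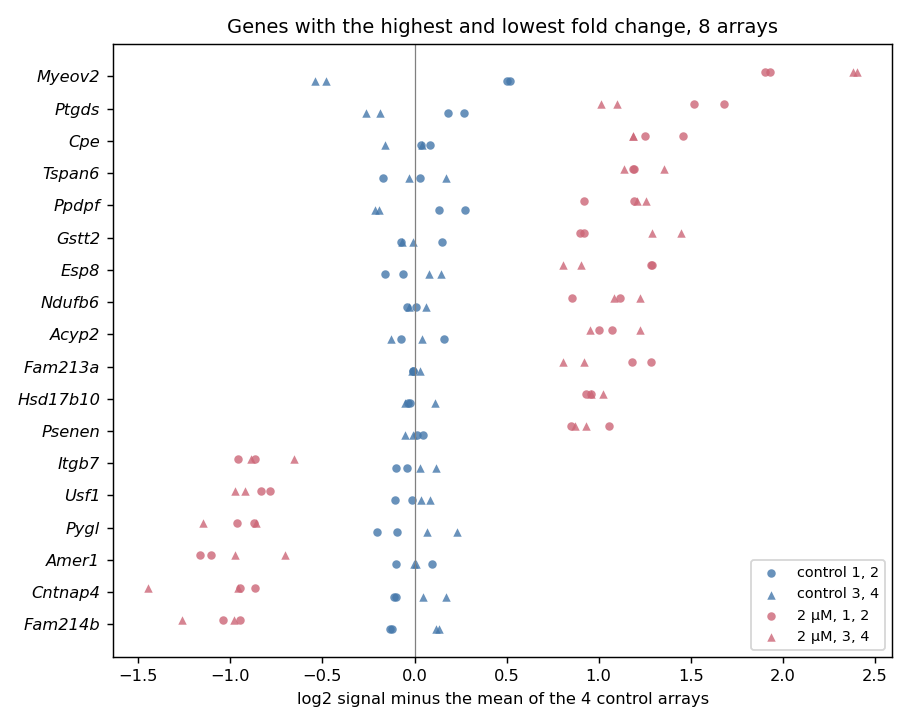
Log2 signal of each array minus the mean of the 4 control arrays, for the 18 named genes with the highest and lowest fold changes. Blue symbols are control arrays and red symbols treated arrays, with circles for arrays 1 and 2 and triangles for arrays 3 and 4. No treated array overlaps a control array, and for Myeov2 the control pairs lie at 7.86 and 6.84 in log2 signal.

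No gene of the melanin list was past the threshold. The melanin enzymes Tyr, Tyrp1 and Dct differed by 0.15 ± 0.15, 0.01 ± 0.15 and 0.08 ± 0.15 (log2 change ± SE, n = 4 arrays per group), and the melanosome matrix protein Pmel by 0.22 ± 0.13. Tyrp1 and Dct, at 19.02 and 18.92 in controls, lay close to the highest signal of any array, 19.74, where saturation can hide a difference. Mitf, the transcription factor that governs the melanocyte lineage, differed by 0.19 ± 0.19. As a list, 15 of the 16 measured genes of melanin synthesis and melanosomes had a positive change, with a median of 0.20 and an adjusted p of 0.0271 (camera), while the adjusted p was 0.454 with an estimated correlation. None was called over all genes, while 3 were higher when adjusted over the list alone, with Slc24a5 at 0.55 ± 0.12 and Slc45a2 at 0.58 ± 0.13, both carriers of the melanosome pathway. In the authors' deposited table the median of this list was -0.054.

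Lists of stress signalling and of immediate early genes were also called higher in the treated arrays. For the integrated stress response and ATF4 targets, 20 of 24 members had a positive change and the median was 0.23 (camera adjusted p = 0.00871, or adjusted p = 0.479 with an estimated correlation). Its median was 0.48 in treated arrays 1 and 2 and 0.16 in treated arrays 3 and 4, each against all controls. The largest among its 4 named members was Chac1, a glutathione-degrading enzyme, at 1.43 ± 0.39, followed by Pck2 at 0.62 ± 0.17, Asns at 0.48 ± 0.15 and Cebpb at 0.43 ± 0.13. Immediate early genes had a median of 0.23 with 13 of 17 positive (camera adjusted p = 0.0218, or adjusted p = 0.454 with an estimated correlation). The medians by treated pair were 0.28 in arrays 1 and 2 and 0.21 in arrays 3 and 4. Among these, Dusp1, a MAP kinase phosphatase, was at 0.83 ± 0.22, and Btg2, an antiproliferative factor, had a control mean of 4.88, within the background medians. Adjusted over the list alone, 4 members of the stress list and 2 of the immediate early list were higher, and over all genes 0 were, with limma.

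Replication-dependent histone genes had a median of 0.40 with 10 of 12 positive (camera adjusted p = 0.0155, or adjusted p = 0.481 with an estimated correlation). The medians by treated pair were 0.43 in arrays 1 and 2 and 0.23 in arrays 3 and 4. Hist1h1c was at 0.67 ± 0.15 and Hist1h3c at 0.61 ± 0.15, and 3 members were higher when adjusted over the list alone. The mitochondrial respiratory chain had a median of 0.23 with 20 of 28 positive (camera adjusted p = 0.0218, or adjusted p = 0.764 with an estimated correlation), and 5 members were higher adjusted over the list alone, among them Ndufs3 at 0.66 ± 0.17 and Sdhc at 0.61 ± 0.17. Its median was -0.071 in treated arrays 1 and 2 and 0.44 in treated arrays 3 and 4, each against all controls. These were 5 of the 37 lists, and 0 of them passed with an estimated correlation, where 2 lists had an unadjusted p under 0.05.

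Among the genes fixed for naming in any case, Cdkn1a, which encodes the p21 inhibitor of cyclin-dependent kinases, had the widest spread in the treated arrays. It was at 10.06 ± 0.11 in controls and 12.07 ± 1.48 in treated arrays (SD, n = 4 each), with a mean of 13.35 in treated arrays 1 and 2 and 10.79 in arrays 3 and 4. Its change of 2.01 ± 0.58 (SE) had an adjusted p of 0.136 (limma). Mki67, a proliferation marker, differed by -0.47 ± 0.21. Ddit3 differed by 0.13 ± 0.14 and Hmox1 by 0.38 ± 0.49. None of these passed the threshold. Markers of fibroblasts, keratinocytes, leukocytes and endothelium, read as a check on other cell types, had medians of -0.05, 0.02, -0.14 and -0.12, and none of these lists was called.

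The second source, the authors' deposited table, has a treated average that was not matched by any of 255 averages over the 8 arrays (median absolute difference of 0.17 or more on the log2 scale), so it is described on its own. The highest 3 named genes in the authors' deposited table belong to the list of NRF2 and oxidative stress genes. Srxn1, which repairs oxidised peroxiredoxins, was 6.28-fold higher (FDR 0.0196) in the authors' deposited table. Hmox1, which degrades heme, was 3.99-fold higher (FDR 0.0417), and Gclm, a subunit of the enzyme that starts glutathione synthesis, 3.32-fold higher (FDR 0.0468), in the authors' deposited table. The metallothionein gene Mt2 was 3.20-fold, Fstl1 3.03-fold and Creld2, a chaperone of the endoplasmic reticulum, 2.69-fold higher in the authors' deposited table. P4hb, Blvrb, Atp5l, Mgst1, Osgin1 and Gadd45a followed with 2.39-fold to 2.49-fold in the authors' deposited table.

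Among the lowest, Adck3 (now Coq8a) had a log2 change of -1.35, Prex2 and Prune2 of -1.24 each, Spsb1 of -1.14 and Cpne4 of -1.02 in the authors' deposited table. Tonsl, a factor of replication fork repair, Murc (now Cavin4), Ttc23l, the NADPH oxidase gene Nox4, Ccdc106, Tnnt3 and Eqtn were also lower, but their treated averages in the authors' deposited table were below 5.17, the background level named for the arrays, so no size is given. The control averages of Ccdc106, Tnnt3 and Eqtn were below it as well in the authors' deposited table. In total the authors' deposited table held 347 transcript clusters with an FDR under 0.05, 199 higher and 148 lower, and 66 of them at least 2-fold (54 higher, 12 lower). In the arrays, none of these 24 genes passed the threshold. Srxn1 differed there by -0.19 ± 0.34, Gclm by -0.11 ± 0.25, Creld2 by 0.25 ± 0.14, Mt2 by 1.23 ± 0.27 and Prune2 by -1.10 ± 0.23 (SE, n = 4 per group).

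**Figure D3:**
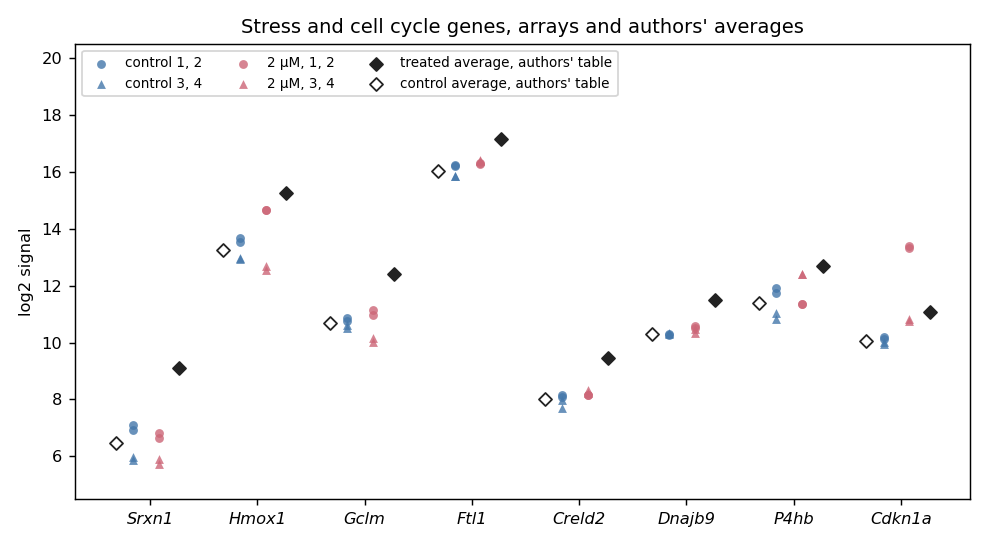
Log2 signal of 8 genes in each array (blue control, red treated, circles arrays 1 and 2, triangles arrays 3 and 4) and the group averages of the authors' deposited table (open diamonds control, filled diamonds treated). The open diamonds lie among the control arrays, while the filled diamond of Srxn1, at 9.12, lies above all 8 arrays.

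Grouped by the fixed lists, chaperones of the unfolded protein response stood out in the authors' deposited table. All 19 measured members had a positive log2 change there, with a median of 0.83 at percentile 100 of random lists in the authors' deposited table. Of these, 4 had an FDR under 0.05 and 12 when adjusted over the list alone, including Dnajb9, Calr (1.24) and Pdia3 (1.06 on the log2 scale) in the authors' deposited table. The NRF2 and oxidative stress list had 22 of 23 positive, a median of 0.75 at percentile 100, 7 members with an FDR under 0.05 and 17 adjusted over the list alone in the authors' deposited table. Beside Srxn1, Hmox1 and Gclm these were Ftl1 (1.12), a ferritin chain, G6pdx (1.24), Sod1 (0.71) and Sod2 (0.61 on the log2 scale) in the authors' deposited table. In the arrays the medians of these lists were 0.12 and 0.21, with camera adjusted p of 0.351 and 0.180.

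Ribosomal and respiratory genes were also shifted in the authors' deposited table. All 26 cytosolic ribosomal protein genes were positive, with a median of 0.48 at percentile 100 and 2 past the FDR threshold, Rpsa (0.60) and Rpl27 (0.73), in the authors' deposited table. Ribosomal and respiratory genes varied together in the arrays, with estimated inter-gene correlations of 0.688 and 0.394, which random lists do not carry. The respiratory chain had a median of 0.48 at percentile 100, with 25 of 28 positive and 3 past the threshold, Cox4i1, Ndufb3 and Cox7a2, in the authors' deposited table. Autophagy and lysosome genes had a median of 0.33 with 24 of 27 positive, Lamp1 and Sqstm1 being past the threshold, in the authors' deposited table. Cholesterol efflux genes, with a median of 0.23, and the integrated stress response, with 0.21 and Ppp1r15a and Nupr1 past the threshold, were at percentiles 97.7 and 99.5 in the authors' deposited table. DNA replication genes had a median of -0.28 with 23 of 27 negative, below all random lists, and Uhrf1 (-0.81) past the threshold in the authors' deposited table. Glycolysis and hypoxia genes had a median of -0.23 with 19 of 24 negative and none past the threshold in the authors' deposited table, where 5 were lower adjusted over the list alone. In the arrays the glycolysis list had a positive median, 0.08, with 15 of 24 positive, DNA replication was at 0.00 with 14 of 27 positive, and the ribosomal, autophagy and efflux lists were at 0.14, 0.16 and 0.27. The ribosomal median was -0.19 in treated arrays 1 and 2 and 0.43 in treated arrays 3 and 4, and the efflux median 0.44 and 0.07. Camera without a block called none of these 5 lists in the arrays, with adjusted p of 0.0912 to 0.784. With the pair as a random block, camera at the preset correlation called the efflux and autophagy lists (adjusted p of 0.0242 and 0.0405). Passing it does not account for the pairs, since this test takes genes as its units. With means of close pairs, camera called neither list. With an estimated correlation and no block, their camera adjusted p were 0.481 and 0.479. The fry list test, also without a block, called the autophagy list (adjusted p of 0.0476) but not the efflux list (0.101). Without a block, fry takes the arrays of a close pair as independent.

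**Figure D4:**
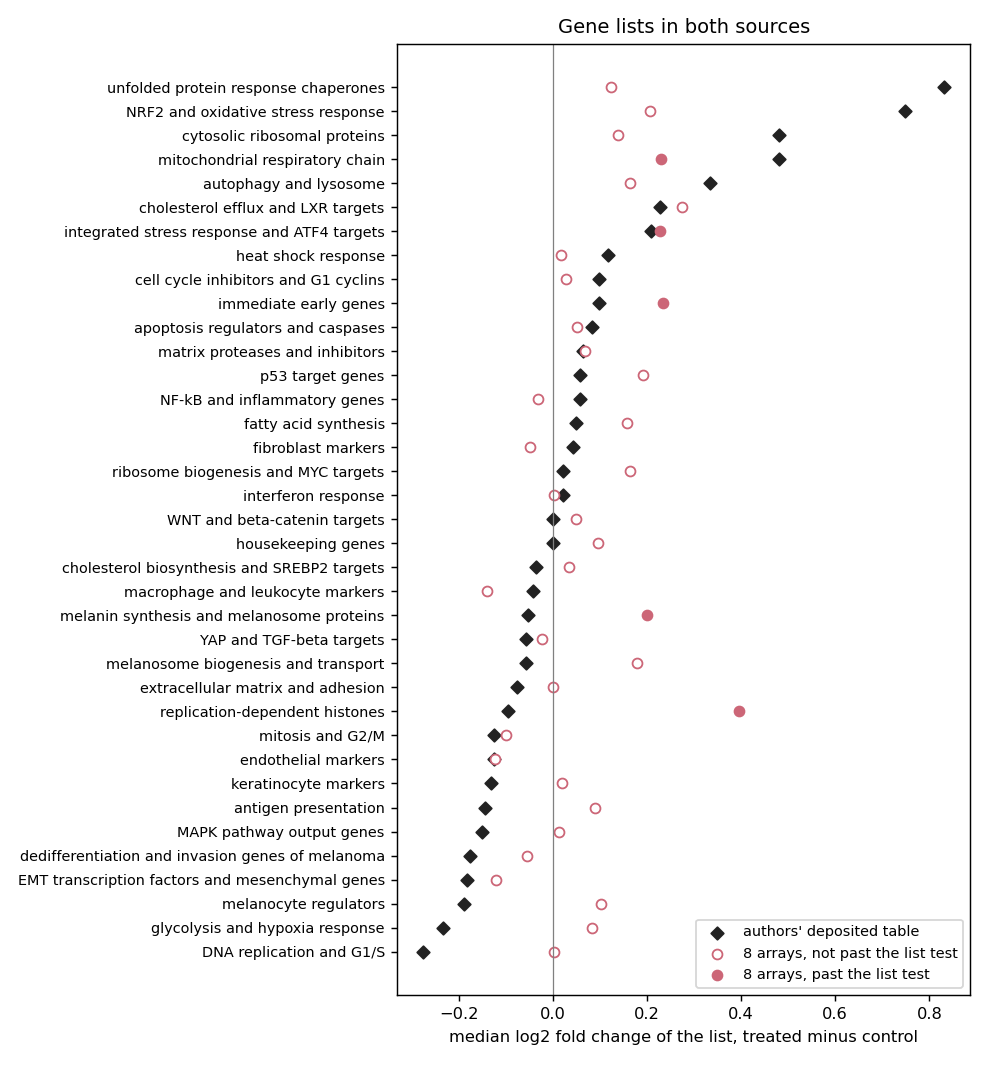
Median log2 fold change, treated minus control, of the 37 gene lists. Filled red circles are the 5 lists past the camera test in the 8 arrays, open red circles the other lists in the arrays, and black diamonds the authors' deposited table, where the chaperone list reaches 0.83 and the DNA replication list -0.28.

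Set against each other, the 2 sources shared 9 called transcript clusters, all in the same direction, where 0.212 would be shared by independent lists, a value that leaves out the shared controls. They were Ptgds, Hsd17b10, Psenen, Amer1, Pygl, Usf1, Taf10, Gm11808 and Gm5142. Of the 347 called in the authors' deposited table, 288 (83.0%) had the same sign in the arrays, while unchanged arrays simulated against shared controls gave 74.9% with noise taken per group and 92.3% with noise pooled over groups. Both sources use the same 4 control arrays, so some likeness arises with no effect at all. Across all transcript clusters the fold changes correlated at 0.353 (covariance 0.0354), and the same simulations gave 0.348 (covariance 0.0434) and 0.502 (covariance 0.0623). With control arrays 1 and 2 used for the arrays and 3 and 4 for the authors' deposited table, the correlation was -0.0275, and -0.0776 the other way round. Transcript clusters are not independent replicates in any of these correlations.

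**Figure D5:**
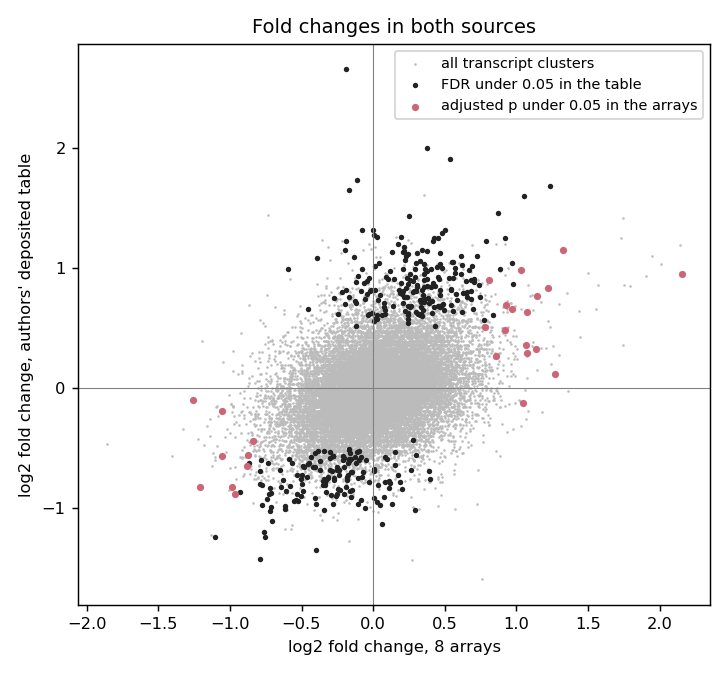
Log2 fold change of each of 22206 transcript clusters in the 8 arrays (horizontal) and in the authors' deposited table (vertical). Black points are the 347 with an FDR under 0.05 in the authors' deposited table and red points the 26 called in the arrays; 9 are called in both.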

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

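Of the tests in this part, those on the treated average of the authors' deposited table were chosen after the result was seen, as were the fits that use the close pairs.

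In 5 of 136 groups of 4 arrays, a single array lay apart from the other 3 by more than Dixon's critical gap. Chance alone sets apart about 5% of such groups if the 4 arrays are independent. With close pairs this share need not hold, so it is no fair reference here. The gaps were those of control array 4 for Fam213a (0.866 of the range), control array 3 for Hsd17b10 (0.845), treated array 3 for Cntnap4 (0.835), control array 1 for Vmn2r53 (0.842) and control array 1 for Blvrb (0.830). The hybridization spike-ins, which are added after labelling and enter no comparison, were brighter on each of the 4 treated arrays than on any control array, with a difference of the group means of 0.17 on the log2 scale.

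The first pattern is the fall of the 8 arrays into 4 close pairs. Labelling or RNA handling shared within a pair could give it: the 4 poly-A spike-in probe sets, for RNA added before labelling, differed 7.44 times as much between pairs of a group as within pairs. This ratio was 1.25 to 3.86 for the transcript clusters and the other kinds of control. Hybridization or scanning shared within a pair cannot be told apart from it, because the antigenomic background probe sets gave no common answer, with partner correlations of 0.878, -0.959, 0.394 and -0.123 over 23 probe sets. A culture or a day shared within a pair stays open, since the labels name neither, and no biological explanation was tested.

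The second pattern is that the treated average of the authors' deposited table differs from the arrays labelled 2 µM. Another way of averaging is argued against, since the averaging that gives the control column leaves 2.40% of the treated values of the authors' deposited table within 0.01, and 4512 of its 22206 treated averages lie outside the range of all 8 arrays, where no average can fall. Among the 347 transcript clusters called in the authors' deposited table, which were called on that same average, 279 lie outside this range. Other treated cultures with a response shared over all genes cannot be told apart from chance: fold changes taken against separate control pairs correlated at -0.0275 and -0.0776, but at 0.0474 and 0.0655 for treated arrays 3 and 4 alone, which with shared controls reached 0.473 against 0.125 for treated arrays 1 and 2. A response shared by the genes called in the table cannot be told apart from chance either: 78.7% and 83.0% had the same sign against separate control pairs, while simulations with unchanged arrays gave 72.9% or 86.8% depending on the noise assumed, and those genes were called with the same controls. Whether that column, or the treated arrays themselves, belong to cultures at 0.2 µM, the dose in the treatment note of the controls, was not tested.

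The third pattern is the set of 5 gene lists called in the arrays. A difference between pairs within a group could give it: for 3 of the 5 lists, a within-group difference between pairs was at least as large as the difference between treated and control arrays. Of the 35 ways to split the 8 arrays into groups of 4, 2 gave as many called lists, the real one included, with 5 in the real split and 5 as the highest of the others, so chance cannot be excluded. The other split with 5 parts close pairs, and the 3 splits that keep all pairs gave 5 (the real one), 4 and 2 lists. An effect of the compound stays open, and these fits do not decide it. At the preset correlation camera called these 5 with the pair as a random block (adjusted p of 0.00156 to 0.0124) and with means of close pairs. With an estimated correlation and no block it called 0 (adjusted p of 0.454 to 0.764), with 2 of the lists tested at an unadjusted p under 0.05. The preset test takes genes as its units at a correlation of 0.01, so passing it with the block does not account for the pairs. The estimated correlation was 0.394 for the respiratory chain, 0.258 for the histones and -0.00207 to 0.0783 for the other called lists.

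For the count of changed genes, 3 of the 35 splits, the real one included, gave as many as the real 26, so chance cannot be excluded. These 3 are the only splits that keep all close pairs, and the real one gave the fewest genes of them. Every split that parts a pair gave 0 genes, so those splits are no fair reference for chance. The highest was 1562, with control arrays 1 and 2 and treated arrays 1 and 2 on the same side, and the other gave 493, with control arrays 1 and 2 beside treated arrays 3 and 4. Both keep all 4 close pairs whole, as the real split does, which points to the pairs as a structure of the samples. With the pair as a random block, 0 genes were called in the real split (limma; 890 at an unadjusted p under 0.05).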

How the results depend on the processing

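The pair as a random block, means of close pairs and the fits without 2 arrays were chosen after seeing the data. The causes of the changes below were not tested, except where fewer arrays or fewer transcript clusters enter by construction. Signal over background limits the dim genes, since the antigenomic background had medians of 4.69 to 5.17 on the log2 scale. Mean signals were below 5.17 for Gstt2, Esp8, Cntnap4, Vmn2r53 and Gm5142 in both groups, for Acyp2 and Btg2 in controls and for Fam214b and Gm4297 in treated arrays.

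The 8-array fit gave 26 changed genes, 17 higher, 9 lower, 15 changed at least 2-fold and 5 lists. With each array centred on its median there were 48 changed and 40 higher. Without the dim lower 50 percent there were 56 changed, 41 higher and 15 lower, of which 19 were among the 26. Quantile normalization again left 3 lists and 25 genes, of which 21 were among the 26. The camera test with an estimated correlation called 0 lists, with 2 at an unadjusted p under 0.05, while fry called 7, with the melanin, integrated stress and immediate early lists among them but not the respiratory chain (adjusted p 0.302) or the histones (adjusted p 0.0573). The treat test against a fold of 1.2 called 0 genes, with 1076 at an unadjusted p under 0.05. With the authors' table as the source there were 347 changed, 199 higher, 148 lower and 66 changed at least 2-fold.

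With the replicate number as a block, limma called 0 genes changed, 0 higher, 0 lower and 0 at least 2-fold, with 4320 at an unadjusted p under 0.05. Same-numbered arrays deviated together with correlations of 0.0696, 0.0839, 0.0793 and 0.0746, too low to take the numbers as pairs. Since partners are near copies, these 4 values are not separate checks and cannot tell number 1 from 2 or 3 from 4. Every array correlated best with its close partner of another number.

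Leaving out each array in turn gave 0 to 5 genes changed, 0 to 3 higher, 0 to 2 lower, 0 to 5 at least 2-fold and 3 to 6 lists, with 3 lists without control array 3, control array 4, treated array 3 or treated array 4. Without treated array 4 there were 5 genes, and without any other array there were 0, with 3089 to 4401 at an unadjusted p under 0.05.

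With the pair as a random block limma called 0 genes changed, 0 higher, 0 lower and 0 at least 2-fold, with 890 at an unadjusted p under 0.05, and there were 8 lists. With means of close pairs there were 0 changed, 0 higher, 0 lower and 0 at least 2-fold, with 571 at an unadjusted p under 0.05. The 890 and the 571 are each a share below 0.05 of the transcript clusters tested, which chance alone can give. The means gave the 5 lists of the 8-array fit but not the other 3, which were p53 targets, cholesterol efflux, and autophagy and lysosome. Without treated arrays 1 and 2 there were 881 changed, 476 higher, 405 lower, 124 at least 2-fold and 3 lists. Without treated arrays 3 and 4 there were 5502 changed, 3094 higher, 2408 lower, 1050 at least 2-fold and 3 lists. All 26 genes were among the 881 and among the 5502. Each fit without 2 arrays leaves 1 close pair as a whole group, whose spread is then only that between partners. Its counts can be inflated by this, and the presence of the 26 in both sets is no independent support. Without control arrays 1 and 2 there were 24 genes at least 2-fold, and 4 of the 24 changed were among the 26. Without control arrays 3 and 4 there were 0 changed, 0 higher, 0 lower and 0 at least 2-fold, with 3997 at an unadjusted p under 0.05, and 1 list.

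Some directions turned with the source. In the authors' table the melanin list had a median of -0.054, the histone list -0.096 and Fam213a a log2 change of -0.12. In the 8 arrays in place of the authors' table, Srxn1 was at -0.19, Gclm at -0.11, Blvrb at -0.076, Spsb1 at 0.061 and Cpne4 at 0.29. The respiratory chain median was -0.071 without treated arrays 3 and 4. The 26 genes and the other called lists kept their direction in the fits to the array values, though many calls were lost. Over all alternatives the 26 and the other named genes of the arrays stayed on the same side of the threshold 916 times. They fell below it 358 times and passed it newly 25 times. The 916 include genes called in neither fit, while all 358 losses are of the 26. In the alternative fits to the array values, each of the 26 kept its call in a minority to 50% of them, from 6 of 20 for Cntnap4 to 11 of 22 for Cpe. Trend and robust variance, array weights (whose fit stopped before convergence), 1 transcript cluster per named gene and removal of transcript clusters below 4.21 kept each gene count within 1.5 times.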

Other observations

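Gene families, taken as symbols with the same letters before the first digit and at least 20 members, were compared with random lists after the data had been seen. Members of a family can vary together, which random lists do not carry. In the authors' deposited table the Rpl and Rps families, named for the 2 subunits of the cytosolic ribosome, were highest of the 90. Of 41 Rpl genes 40 were positive with a median of 0.60, and of 38 Rps genes 32 with a median of 0.49. Symbols alone define these families, so they can hold genes that encode no ribosomal protein. The mitochondrial ribosome followed in the authors' deposited table, with medians of 0.38 for 47 Mrpl genes and 0.37 for 28 Mrps genes, then the 26 Cox genes with 0.36 and the 29 Sec genes with 0.26. The 59 histone genes (Hist) had a median of -0.18 and the 23 cadherin genes (Cdh) of -0.25 in the authors' deposited table.

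In the arrays, the Zdhhc genes, which encode enzymes that attach palmitate to proteins, had the highest median of the 6 families in the top 2.5% of random lists, at 0.34 with 17 of 24 positive, and 0.43 in treated arrays 1 and 2 against 0.11 in treated arrays 3 and 4. The Mrpl genes were at 0.21 with 38 of 47 positive, the tetraspanins (Tspan) at 0.22 with 14 of 20 positive, and the histone genes at 0.18 with 52 of 59 positive. For the histone genes the control pairs differed by 0.50, more than the groups, and for the Mrpl genes the treated pairs differed by 0.26. The centrosomal Cep genes had the lowest median of the 5 families in the bottom 2.5%, at -0.25, with -0.56 in treated arrays 1 and 2 and 0.00 in treated arrays 3 and 4. The Rpl genes were at -0.20 in treated arrays 1 and 2 and at 0.49 in treated arrays 3 and 4, each against all controls, and these differences between pairs were not tested. The medians over the 8 arrays given here kept their sign under quantile normalization and median centring. Of these families, Rpl37a and Tspan6 were the only genes called over all transcript clusters, and 1 family, Mrpl, was in the top 2.5% in both sources and 3 (Cdh, Kif and Zfp) in the bottom 2.5%, where the shared controls alone can give some likeness.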
